A study of Rattus norvegicus with 69 samples.

How the data were processed

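RNA was measured on Affymetrix rat arrays in 69 samples from Sprague Dawley rats, with 1 array per sample. Of these, 49 were seminiferous tubules that the authors had dissected under transillumination into 10 stages or groups of stages of the seminiferous epithelium cycle. Each tubule sample pooled tubules from 2 rats aged 55 to 60 days, with 25 segments per rat. The other samples were isolated cells and whole testis: 4 samples of Sertoli cells, 4 of round spermatids, 4 of pachytene spermatocytes, 3 of spermatogonia plus early spermatocytes and 5 of whole testis. Sertoli cells and the 2 later germ cell groups came from rats aged 55 to 60 days, and spermatogonia plus early spermatocytes from rats aged 18 to 20 days. The age behind the whole testis samples was not given in the sources used here. Per the labels, Sertoli cells were about 85% pure, and the germ cells, separated by centrifugal elutriation, were 85% to 95% pure. The stage groups were taken from the sample titles. For the group called IX-XI here, the titles and the protocol gave IX-XI and the source names IX-XII, so that its samples may hold stage XII tubules as well, and the labels do not settle it. Stage IV-V had replicates 2 to 5, since no replicate 1 was listed.

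Per the labels, total RNA was extracted with Trizol and purified on RNeasy columns, biotinylated cRNA was made from 6 µg, and the processing notes named MAS5, with no version. The deposited values gave 1 signal intensity per probe set and sample on a linear scale, with every value above 0. The authors had scaled each array: after removal of 2% of probe sets at each end, the mean intensity was 100 in every array. No step between arrays beyond this scaling was found in the values. The scaling target and any filter were not given in the sources used here, and no detection calls were part of the table, so that a low signal was not shown to lie above background. Of 31099 probe sets, 57 controls were left out and 31042 were used. The number of arrays, 3 to 5 per group, limits the precision of every mean.

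Gene symbols came from the platform's table of probe sets, which paired 20826 probe sets with exactly 1 gene and 436 with several, and did not list 9780. Symbols of 20758 probe sets were brought up to date through a RefSeq gene table of the rat assembly GRCr8, and 68 kept the platform's symbol. In all, 14217 genes were represented. No coordinates are given.

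Values were analysed as log2 of the signal plus 5.11, the 10th percentile of the table, in R 4.3.3 with limma 3.58.1 (linear model and moderated statistics with a trend of variance on mean level) and the package data.table, version 1.17.8. A probe set was tested when its signal exceeded 43.7, the median of the table, in at least 3 samples of the fit. p-values were adjusted by the Benjamini-Hochberg method within each contrast, and limma's contrasts, camera and Fisher's test were two-sided. Fold changes are those of the log2 scale with 5.11 added, which makes them smaller than the ratio of signals for weakly expressed genes. Stage-regulated probe sets passed limma's F-test over the 10 stages at an adjusted p under 0.05 and had at least 2-fold between their highest and lowest stage means. The 10 pairs of adjacent stages were contrasted in the same fit. In a fit of the 15 isolated cell samples, Sertoli cells were contrasted with the mean of the 3 germ cell groups, pachytene spermatocytes with spermatogonia plus early spermatocytes, and round spermatids with pachytene spermatocytes. Whole testis was contrasted with the mean of the 10 stage means. Changes counted when the adjusted p was under 0.05 and the change at least 2-fold. A probe set was called enriched in a cell group when it was at least 4-fold higher there than in each of the other 3. The share of enriched probe sets that were stage-regulated was compared with that of the other tested probe sets by Fisher's exact test, and the distribution of their peak stages by a permutation test.

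Before the data were examined, 19 gene lists were fixed: Sertoli cell, spermatogonia, meiotic recombination and synaptonemal complex, pachytene spermatocyte, DNA replication, G2 and M phase, acrosome and round spermatid, elongating spermatid chromatin and flagellum, Leydig cell, peritubular myoid cell, macrophage and blood, endothelial cell, retinoid metabolism, cell junction, proteases and inhibitors, cholesterol synthesis, X-linked housekeeping genes, autosomal retrogenes of X-linked genes, and immediate early and heat shock genes. They held 295 names, of which 234 were measured. A few genes stand in more than 1 list, such as Ctsl (Sertoli cell, proteases) and Cldn11 (Sertoli cell, junctions). Lists were tested against the other genes with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, and the number of stage-regulated members with Fisher's exact test, each adjusted over the 19 lists. A gene with several probe sets was represented by the one with the highest mean.

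Genes to be named followed a rule that was set in advance as well. These were the 2 genes with the largest range at each peak stage, the 6 with the largest change each way in each cell contrast, the 3 stage-regulated genes with the largest margin in each enriched class, the 5 with the largest change each way in whole testis, and up to 4 members of each list. Outside the whole testis contrast, the genes named for their rank had samples that did not overlap between the groups compared. Any other gene named was chosen after its values were seen.

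Alternatives set in advance were a pseudocount of 1, no filter on low values, quantile normalization of the arrays in the fit, the replicate number as a block, and leaving out each sample in turn. Leaving out the tubule samples numbered 1 was added after the data were seen. The steps were tested on simulated data with changes of known size. For the stage test, 45 of 50 simulated 2-fold changes and 50 of 50 simulated 3-fold changes were recovered among 22527 probe sets, with 6 false calls. For round spermatids against pachytene spermatocytes, 18 of 50 at 2-fold and 48 of 50 at 3-fold were recovered among 16884 probe sets, and for whole testis against tubules 31 of 50 at 2-fold among 22649. Pachytene-enriched probe sets were recovered in 7 of 50 cases at 4-fold and 49 of 50 at 8-fold among 16933. Changes were seeded only in probe sets whose mean level was more than 2-fold above the table's median, and values were drawn independently for each probe set. These counts therefore do not show the recovery of changes in weakly expressed probe sets.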

Results

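In the seminiferous tubules of the testis, germ cells develop from spermatogonia through meiotic spermatocytes to spermatids while attached to Sertoli cells, the somatic cells of the epithelium. The cell types that lie together along a tubule change in a repeating order of stages, the cycle of the seminiferous epithelium. RNA levels were measured in 69 samples, of which 49 were rat tubules dissected into 10 stage groups, with 5 samples per group and 4 for stage IV-V. The isolated cells were 4 samples of Sertoli cells, 4 of pachytene spermatocytes, which are in meiotic prophase, 4 of round spermatids, which are haploid cells just past meiosis, and 3 of spermatogonia plus early spermatocytes from younger rats. Whole testis gave 5 samples. Levels are given as array signal, as the mean ± SD of a group's samples, and n is the number above unless given.

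The median signal of an array was between 30.9 and 58.2. It was lowest in Sertoli cells (31.4 ± 0.644) and highest in spermatogonia plus early spermatocytes (49.6 ± 7.61), and the stage groups had means of 42.8 to 47.6. The share of probe sets with a signal above 43.7 was 41.7% to 59.5% per array. Within groups, the mean correlation of an array with the others of its group was between 0.895 and 0.968 across probe sets, which are not independent replicates. The ratio of 3' to 5' signal of the GAPDH control probe sets, which goes up when RNA is degraded, was 2.13 ± 0.306 in round spermatids, 1.22 ± 0.193 in pachytene spermatocytes and 1.10 ± 0.0887 in Sertoli cells. It was 0.958 to 1.56 in the samples of spermatogonia plus early spermatocytes and 1.32 ± 0.137 in whole testis, and among the stage groups it was highest at stage VIIc.d (1.54 ± 0.367). There, replicates 2 and 3 had GAPDH ratios of 1.78 and 2.05, against 1.17 to 1.35 in the others. Their actin ratios were 2.86 and 2.71, against 1.76 to 1.94. The highest ratio for actin, 3.64, was that of replicate 3 of spermatogonia plus early spermatocytes, against 1.54 and 1.88 in the others of this group, and whole testis had 2.02 ± 0.294.

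The stage groups were compared to find the transcripts whose level changed along the cycle. Genes of the acrosome, the enzyme-filled cap of the sperm head, peaked most often at stage VI, and genes for transition proteins and protamines, which pack spermatid DNA, at stages IX-XI. Genes of cell division had most of their peaks at stages XIII-XIV to II-III. The Sertoli cell genes Ctsl, for a lysosomal protease, and Prnd, for a prion-like membrane protein, peaked at stage VIIa.b. Rdh10, for a retinol dehydrogenase, peaked at stage VIII, but was not among the genes called higher in isolated Sertoli cells than in germ cells.

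Of 22258 probe sets tested, 12090 passed limma's F-test over stages after Benjamini-Hochberg adjustment, 7240 of these also differed at least 2-fold between their highest and lowest stage, and 1961 differed at least 4-fold. The 7240 probe sets, called stage-regulated here, represented 5134 of 12003 tested genes with 1 symbol. Peaks were found at every stage group, with 923 at stages IX-XI, 904 at XIII-XIV, 797 at VI, 771 each at IV-V and VIII, 713 at I, 650 at VIIc.d, 606 at II-III, 567 at VIIa.b and 538 at XII. For all genes named from the stage comparison, the samples at the peak stage lay above all samples at the lowest stage, except for Star.

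Prnd went from 2.85 ± 1.96 at stages XIII-XIV to 1881 ± 118 at stage VIIa.b (242-fold with 5.11 added to each signal, adjusted p = 5.65e-30). Signals under 5.11 were not shown to lie above background, so that the size of a fold against such a level, here and in the cell contrasts, depends on the constant added. Fam209, a gene with spermatid expression, had 3053 ± 203 at stage VIIa.b and 10.6 ± 8.43 at XIII-XIV (215-fold, adjusted p = 3.31e-31). At stage VI, the sperm hyaluronidase gene Spam1 reached 2713 ± 226 against 21.2 ± 6.97 at stage XII (106-fold, adjusted p = 4.54e-29), and Tmem89, for a membrane protein, reached 1246 ± 59.0, 81.2-fold over stage XII. At stages IX-XI, the ketone-body enzyme gene Oxct2b reached 3583 ± 584, 107-fold over stage IV-V (adjusted p = 3.69e-27), and the serine protease gene Prss37 reached 4465 ± 977, 106-fold over stage IV-V. Tekt5, for a flagellar filament protein, was 80.9-fold higher at stage VIIc.d than at stage I, and Rhbdd1, for a rhomboid protease, peaked there at 1419 ± 80.8, with 1 other probe set of Rhbdd1 not stage-regulated. Garin4 and Dynlt5 peaked at stage VIII, at 1496 ± 63.4 (77.5-fold) and 1406 ± 152 (62.4-fold). Itih3 and Pierce1 peaked at stage IV-V, at 1668 ± 190 (69.1-fold) and 836 ± 52.4 (35.1-fold).

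The ranges of the genes with the largest ones at the remaining stages were smaller. Smco4 and Numbl peaked at stage II-III with 30.1-fold and 30.0-fold, and the mitotic kinesin gene Kif18b (456 ± 62.6) and the DNA polymerase alpha subunit gene Pola2 (234 ± 36.2) peaked at stage I with 23.0-fold and 17.3-fold. Zbtb5 and Sptbn4 peaked at stages XIII-XIV with 23.7-fold and 21.6-fold. At stage XII, Phf2, for a histone demethylase, was 18.2-fold over its lowest stage (696 ± 184) and Gstp1, for a glutathione transferase, 13.8-fold.

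**Figure D1:**
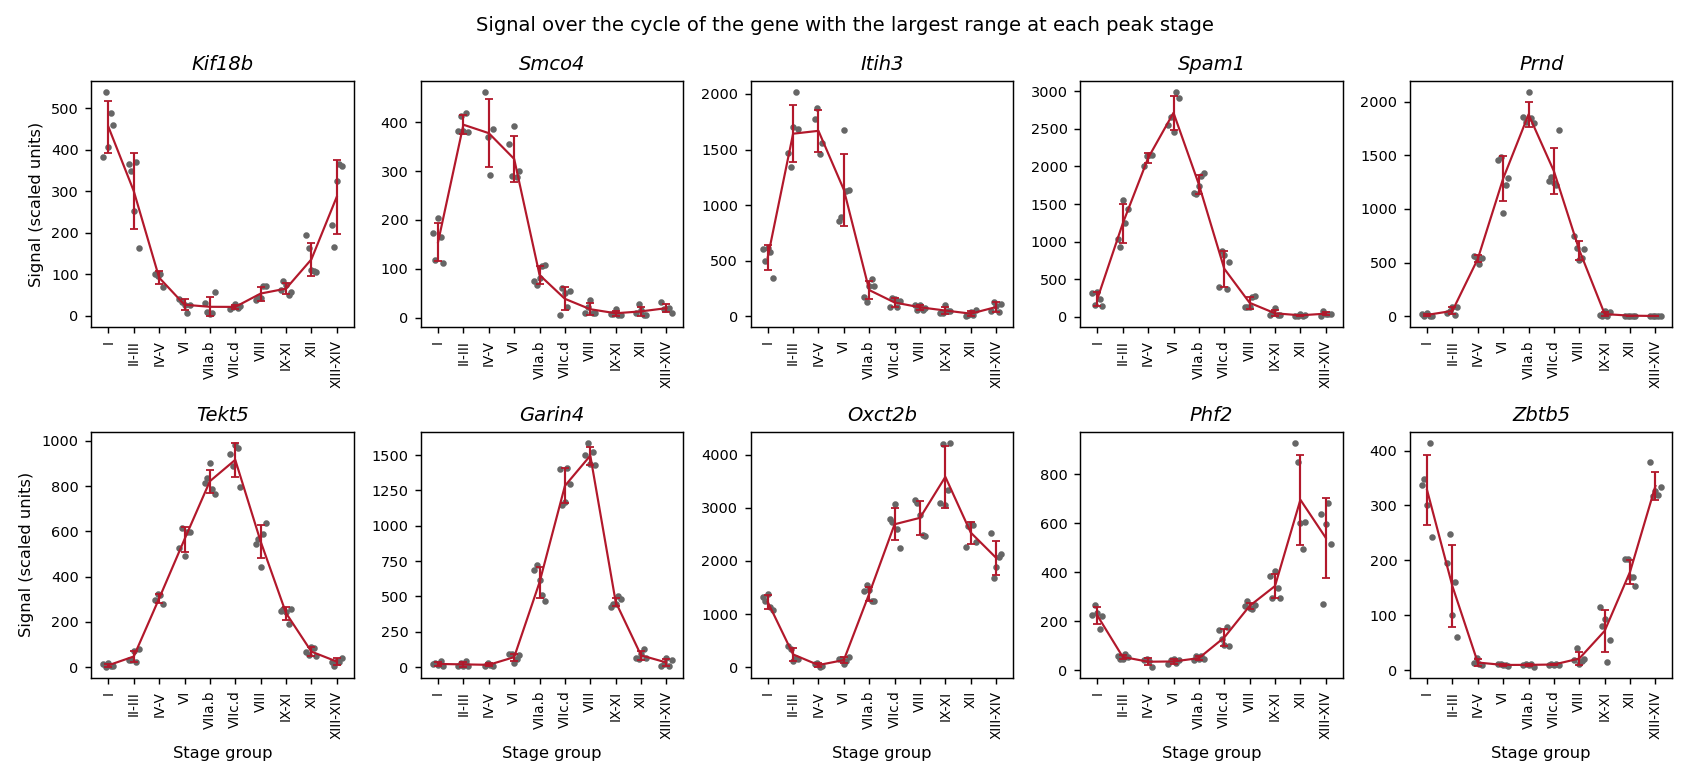
Array signal (y axis, linear) against stage group for the gene with the largest range at each peak stage, with 1 point per sample, lines through the stage means and bars of 1 SD. Prnd rises to 1881 at stage VIIa.b and falls to 2.85 at XIII-XIV, and Spam1 peaks at stage VI at 2713.

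Between adjacent stages, the number of changed probe sets differed from step to step. From stage I to II-III, 518 probe sets rose and 292 fell, a total of 810. From stage VIII to IX-XI, which follow the release of mature sperm, 211 rose and 547 fell, a total of 758. Few changes were found from stage IV-V to VI, with 104, of which 63 rose, and from VIIc.d to VIII, with 118, of which 52 rose. Their order is not settled, as IV-V to VI had 141 without stage VI replicate 1. In between were VI to VIIa.b with 482 (316 higher), II-III to IV-V with 472 (289 higher), XIII-XIV to I with 311 (193 higher), IX-XI to XII with 297 (143 higher), VIIa.b to VIIc.d with 249 (137 higher) and XII to XIII-XIV with 208 (82 higher). Many more probe sets passed limma's test than also changed at least 2-fold, for example 604 from IV-V to VI and 867 from VIIc.d to VIII.

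**Figure D2:**
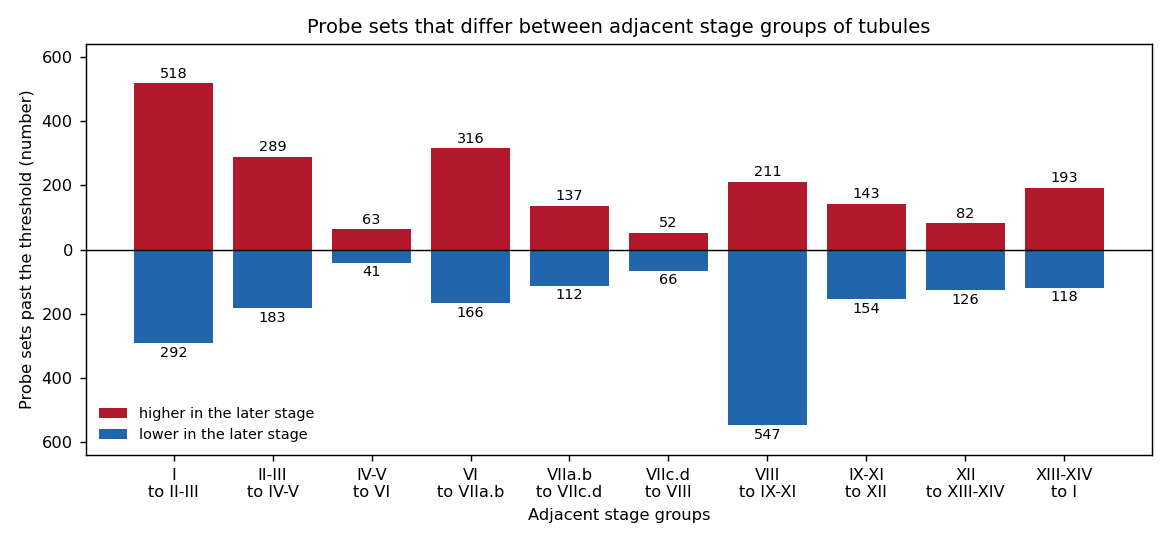
Number of probe sets higher (upward bars) and lower (downward bars) in the later of 2 adjacent stage groups, for each step of the cycle. The steps from I to II-III (810) and from VIII to IX-XI (758) hold the most changes, and IV-V to VI (104) and VIIc.d to VIII (118) hold few.

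Of the gene lists, those for cell division and the acrosome held a larger share of stage-regulated genes than the other genes did. Fisher's exact test took genes as independent, although genes of 1 cell type can rise and fall together over the stages. Its p-values may thus be too small. In the G2 and M phase list, 17 of 20 genes were stage-regulated (Fisher's exact test, odds ratio 9.43, adjusted p = 3.45e-04), with 7 peaks at stage I, 4 at XIII-XIV, 3 at II-III, 2 at XII and 1 at VIII. The kinase genes Plk1 and Aurka were highest at stage I, at 906 ± 65.3 (12.2-fold over stage VIII, adjusted p = 2.46e-25) and 953 ± 155 (10.4-fold over stage VI). The cyclin gene Ccnb1 reached 1137 ± 170 at stage I, 8.41-fold over stages IX-XI. In the acrosome list, 10 of 11 genes were stage-regulated (odds ratio 16.6, adjusted p = 0.00387), with 5 peaks at stage VI. Acrv1, for an acrosomal vesicle protein, rose from 74.0 ± 29.1 at XIII-XIV to 2562 ± 187 at VI (34.3-fold, adjusted p = 4.81e-33), and Spaca3 to 3056 ± 453 at VI (28.8-fold).

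Other germ cell lists did not pass this test, although members changed. In the list of elongating spermatid chromatin and flagellum, 8 of 15 genes were stage-regulated (adjusted p = 0.54), and 7 of them peaked at IX-XI. Among these, Prm2 rose from 359 ± 108 at VI to 8135 ± 2075 (22.6-fold, adjusted p = 2.59e-29), Tnp2 to 14511 ± 6999 (16.3-fold), Hils1 to 7916 ± 2728 (12.5-fold) and Tnp1 to 15022 ± 7329 (8.10-fold). RNA quality was uneven among the samples of IX-XI, where the 3' to 5' ratio of actin was 2.65 and 2.72 in replicates 2 and 3 and 1.61 to 1.81 in the others, and the mean correlation with the group was lowest in these replicates, at 0.900 and 0.895. The pachytene list had 6 of 8 genes (adjusted p = 0.282), the meiotic recombination list 5 of 8 (adjusted p = 0.439), the spermatogonia list 5 of 7 (adjusted p = 0.414) and the DNA replication list 6 of 14 (adjusted p = 0.931). Ccna1, for the meiotic cyclin A1, was 12.8-fold higher at stage I than at IX-XI, while another probe set of Ccna1 peaked at XIII-XIV. The crossover gene Mlh3 was 13.6-fold higher at VIIc.d than at II-III. Gfra1, for a growth factor receptor of stem spermatogonia, was 628 ± 84.8 at stage VIII and 42.0 ± 19.0 at stage I (14.4-fold, adjusted p = 8.86e-22). Among the isolated cells, Gfra1 was highest in round spermatids (158), so that its range is not shown to be that of spermatogonia. Pcna, for the replication clamp, peaked at stage VI at 2457 ± 207 (2.30-fold).

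Among somatic and other lists, 4 of 14 Sertoli cell genes were stage-regulated (adjusted p = 0.807). They were Ctsl (2021 ± 98.3 at VIIa.b, 26.7-fold over XIII-XIV, adjusted p = 2.1e-37, with another probe set peaking at VI), the inhibin genes Inhbb (5.20-fold, stage I) and Inha (2.39-fold, II-III), and Shbg, for the androgen-binding protein (3.27-fold, VIII). The retinoid list had 8 of 16 genes (adjusted p = 0.54). Rdh10 rose from 69.1 ± 9.63 at II-III to 2265 ± 151 at VIII (30.7-fold, adjusted p = 1.78e-35), Aldh1a3 peaked at VI (5.03-fold), Stra6, for the retinol receptor, at VIII (3.01-fold) and Cyp26a1, for a retinoic acid hydroxylase, at IX-XI (2.36-fold). The junction list had 5 of 13 genes (adjusted p = 1), among them Nectin2 at IX-XI (4.86-fold, with another probe set peaking at VIIc.d), F11r at VIII (3.69-fold) and Gja1 at VIIa.b (2.43-fold). The protease list had 7 of 15 genes (adjusted p = 0.807), with A2m 14.3-fold higher at IV-V than at IX-XI. The cholesterol synthesis list had 7 of 10 genes (adjusted p = 0.282), with Cyp51 (672 ± 54.1, 18.5-fold) and Sqle (715 ± 62.2, 6.20-fold) highest at stage VI.

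Lists of cells outside the epithelium held few genes that could be tested. The Leydig cell list had 1 stage-regulated gene of 7, the peritubular myoid list 1 of 5 and the endothelial list 1 of 4, and each of these genes, Star, Myh11 and Eng, lost its call when single samples were left out. Star ranged from a log2 change of 0.88 to 1.39 over the alternatives and Myh11 from 0.96 to 1.18, and the adjusted p of Eng from 0.00581 to 0.11. None of 4 macrophage and blood genes passed limma's test, and 0 had an unadjusted p under 0.05. X-linked housekeeping genes had 3 of 17 (Hprt1 3.21-fold, Uba1 3.22-fold, Fmr1 3.35-fold; list adjusted p = 0.414) and their autosomal retrogenes 2 of 3 (Cstf2t and Pdha2; adjusted p = 0.807). The immediate early and heat shock list had 4 of 11 (adjusted p = 1), with Nr4a1 highest at IV-V (221 ± 8.35, 3.39-fold) and Dusp1 at VIIc.d (126 ± 19.1, 2.85-fold). The counts adjusted over the list alone were the same for each list, except for the endothelial list, where no gene passed. The Leydig, macrophage and endothelial lists had adjusted p of 0.54, 0.54 and 1, and the myoid list 0.831. For Ccnb1, Mlh3, Gfra1, Rdh10, Stra6, Gja1 and Myh11, 1 other probe set each was not stage-regulated.

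Sertoli cells were compared with the mean of the 3 germ cell groups to find transcripts of the somatic cells. Sertoli cells had higher levels of Sertoli cell genes such as Shbg, of genes of cell junctions, such as Espn, for an actin-bundling protein of the ectoplasmic specialization, and of proteases such as Ctsl. Genes of cell division and the acrosome were lower, and genes of Leydig, myoid and endothelial cells and immediate early genes were higher, but these 6 lists passed only at the preset correlation between genes and not with an estimated one. Of 20253 probe sets tested, 4886 were higher and 6014 lower in Sertoli cells.

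Among the genes with the largest changes, Prnd was 2567 ± 610 in Sertoli cells and 16.5 ± 13.4 in germ cells (153-fold, adjusted p = 4.14e-13), and Tagln, for a smooth muscle protein, was 825 ± 345 and 2.49 (102-fold, adjusted p = 3.65e-14). Ptgds, for a prostaglandin synthase, was 67.2-fold higher, the peptidase gene Cpe 48.2-fold, the protease inhibitor gene Serpina5 42.2-fold and the cystatin gene Cst9l 40.7-fold. In tubules, which hold Sertoli cells, Tagln was at 4.80 and Cpe at 8.75, and in whole testis they were at 36.9 and 31.9. Prnd, Ptgds, Serpina5 and Cst9l were at 227 to 814 in tubules. Tagln and Cpe are thus not shown to be transcripts of Sertoli cells in the testis. The class II histocompatibility gene RT1-Bb was lower, at 31.5 ± 4.61 against 555 ± 250 (log2 change -3.62, adjusted p = 2.66e-14), followed by Robo2 (-3.50), Pkib (-3.49), Slc22a15 (-3.43), Vnn1 (-3.38) and Fam124a (-3.35). The samples of both sides did not overlap for any of these genes.

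In the Sertoli cell list, 11 of 14 genes were higher and none lower (median log2 change 3.28, camera adjusted p = 1.45e-05, 0.0401 with an estimated correlation), among them Ctsl (27.4-fold), Cst12 (23.8-fold), Shbg (16.1-fold) and Inhbb (15.8-fold). The junction list had 12 of 13 higher (median 3.11, adjusted p = 1.99e-05, 0.0108 with an estimated correlation), with Espn at 1553 ± 214 against 37.7 (36.8-fold), Gja1 at 1910 ± 330 (25.9-fold) and Nectin2 at 1019 ± 126 (20.6-fold), and 1 lower, Nectin3, which spermatids use to hold to Sertoli cells. Proteases and inhibitors had 13 of 15 higher (median 3.05, adjusted p = 1.64e-05, 0.0200 with an estimated correlation). X-linked genes had 14 of 18 higher (median 1.55, adjusted p = 1.64e-05, 0.0196 with an estimated correlation), such as Idh3g (4.49-fold) and Msn (6.98-fold). This list was not higher than in every germ cell group, as its mean log2 level relative to all samples was 1.61 in Sertoli cells, 1.66 in spermatogonia plus early spermatocytes, -1.40 in pachytene spermatocytes and -0.58 in round spermatids. For Shbg, Espn, Gja1, Nectin2, Idh3g and Msn all Sertoli samples lay above all germ cell samples.

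Markers of other cell types moved with the Sertoli cell genes. The Leydig list had 10 of 11 genes higher (median 2.38, adjusted p = 3.44e-04, 0.115 with an estimated correlation), with the steroidogenic genes Hsd11b1 (1006 ± 172, 19.7-fold) and Insl3 (1793 ± 258, 11.3-fold). Cyp17a1 was 1324 ± 208 in Sertoli cells, but 2970 ± 698 in spermatogonia plus early spermatocytes. All 7 myoid genes were higher (median 3.17, adjusted p = 4.74e-04, 0.159 with an estimated correlation), as were all 6 endothelial genes (median 2.70, adjusted p = 0.0104, 0.231 with an estimated correlation), for example Cnn1 (18.5-fold) and Kdr (248 ± 128, 11.7-fold). All 14 immediate early and heat shock genes were higher (median 2.69, adjusted p = 1.45e-05, 0.159 with an estimated correlation), led by Gadd45b (18.9-fold) and Ier3 (2576 ± 366, 17.7-fold). Against spermatogonia plus early spermatocytes alone, neither list was higher, with mean log2 levels relative to all samples of 2.99 in Sertoli cells and 3.18 in spermatogonia plus early spermatocytes for Leydig genes, and of 3.49 and 3.97 for immediate early genes. The macrophage and blood list had 3 of 9 lower (adjusted p = 0.36). Its mean level on the same scale was 0.09 in Sertoli cells, 3.10 in spermatogonia plus early spermatocytes, -0.60 in pachytene spermatocytes and -0.43 in round spermatids, and its median change was no longer negative when any 1 sample of spermatogonia plus early spermatocytes was left out. They were Csf1r (-1.77), Cd68 and C1qb, of which Cd68 (-1.34) and C1qb (-1.13) were less than 2-fold lower with quantile normalization, at -0.87 and -0.68. C1qb was also less than 2-fold lower without Sertoli replicate 2, at -0.94.

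Some germ cell lists were lower in Sertoli cells, while members of others were higher. In the G2 and M phase list, 15 of 20 genes were lower (median -1.31, adjusted p = 1.45e-05, 0.137 with an estimated correlation), with Aurkb at -2.58 and Plk1 at -2.51, from 458 in germ cells to 55.8. The acrosome list had 10 of 11 lower (median -2.37, adjusted p = 2.97e-04, 0.115 with an estimated correlation), with Spam1 at -2.83 and Spaca3 at -2.77. The elongating spermatid list had 9 of 15 lower (median -1.51, adjusted p = 0.086), and it passed without Sertoli replicate 1 (adjusted p = 0.0274) or 2 (adjusted p = 0.0167), in a range of 0.0167 to 0.195 over all alternatives. The spermatogonia list had 5 of 10 genes higher in Sertoli cells (adjusted p = 0.115), led by Uchl1, for a ubiquitin hydrolase (1181 ± 152, 5.85-fold), and also Dmrt1, a transcription factor gene active in Sertoli cells too, Sall4, Sohlh1 and Upp1, while Gfra1 was lower. Samples of Dmrt1, Sall4, Sohlh1 and Upp1 in Sertoli cells overlapped those of germ cells, as did samples of Spam1 and Spaca3, which were low in the earlier germ cells too. The pachytene list had 5 of 8 lower (adjusted p = 0.169), the meiotic recombination list 1 of 7, Smc1b (adjusted p = 0.267), and the DNA replication list 4 higher and 3 lower of 17 (adjusted p = 0.356). The retinoid list had 5 higher and 3 lower of 14 (adjusted p = 0.365), with Aldh1a1 9.42-fold higher. Of the retrogenes, 2 of 3 were lower (adjusted p = 0.365), with Cetn1 at -2.79. For cholesterol synthesis, Dhcr7 was higher and Fdft1 lower of 10 genes (adjusted p = 0.726), and the list's median (-0.01) and mean (0.08) differed in sign. Another probe set of Fdft1 was not called. Counts adjusted over the list alone were the same for every list.

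Pachytene spermatocytes were compared with spermatogonia plus early spermatocytes to follow the entry into late meiotic prophase. Genes of the pachytene list were higher in pachytene spermatocytes, and X-linked housekeeping genes, whose chromosome is silenced in these cells, were lower, as were macrophage genes. Acrosome, elongating spermatid and retrogene lists were higher, and replication, spermatogonia, Leydig and immediate early lists lower, but none of these 7 passed with an estimated correlation between genes. The meiotic recombination list did not pass. Spermatogonia plus early spermatocytes came from rats aged 18 to 20 days and pachytene spermatocytes from rats aged 55 to 60 days. Age and cell type thus went together. In the younger samples, the macrophage, Leydig and immediate early lists were also at medians of 3.47, 3.21 and 4.27 (log2) above tubules. A lower level in pachytene spermatocytes therefore need not be a change within germ cells, and the part of other cells in it was not tested.

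In pachytene spermatocytes, 3749 of 20253 probe sets were higher and 5792 lower. The median log2 change of all probe sets was -0.15, and quantile normalization of the arrays moved it to 0.13, with 4717 probe sets higher and 5015 lower, so that the higher share was 39.3% and 48.5%. The largest rises were in spermatid genes, with Tnp1 at 2283 ± 399 against 1.33 ± 0.605 (352-fold, adjusted p = 7.19e-13), Prm1 at 4027 ± 1008 (263-fold), Tnp2 at 1523 ± 173 (238-fold), the sperm calcium channel gene Catsperz at 2022 ± 238 (175-fold), Cimip4 at 704 ± 89.1 (117-fold) and the flagellar gene Spag16 at 843 ± 128 (112-fold). The chemokine gene Ccl2 fell by 8.34 on the log2 scale, from 3547 ± 1440 to 5.40 ± 1.94 (adjusted p = 1.8e-12). Basement membrane genes Nid1 (-7.17) and Lamb1 (-6.82), the steroid enzyme gene Cyp17a1 (-7.04), the inflammatory regulator gene Nfkbia (-6.80) and the chemokine gene Ccl7 (-6.73) followed. No samples of the 2 groups overlapped for these genes.

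The X-linked list had 16 of 18 genes lower and none higher (median -3.32, camera adjusted p = 1.75e-06, 0.0177 with an estimated correlation). Ddx3x, for an RNA helicase, went from 1506 ± 293 to 31.3 ± 11.2 (-5.41, adjusted p = 1.4e-13), Fmr1 from 219 ± 20.0 to 2.56 ± 2.20 (-4.91), and Hprt1 from 913 ± 125 to 62.8 ± 7.97 (-3.76). Of the autosomal retrogenes, 2 of 3 were higher (median 2.15, adjusted p = 0.0332, 0.0782 with an estimated correlation), Cetn1 from 31.0 ± 20.0 to 1947 ± 277 (59.0-fold) and Pdha2 from 206 ± 43.7 to 919 ± 91.3 (4.43-fold). With quantile normalization the retrogene list's adjusted p was 0.0872, in a range of 0.0185 to 0.0872 over the alternatives. In none of Ddx3x, Fmr1, Hprt1, Cetn1 and Pdha2 did samples of the 2 groups overlap.

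**Figure D3:**
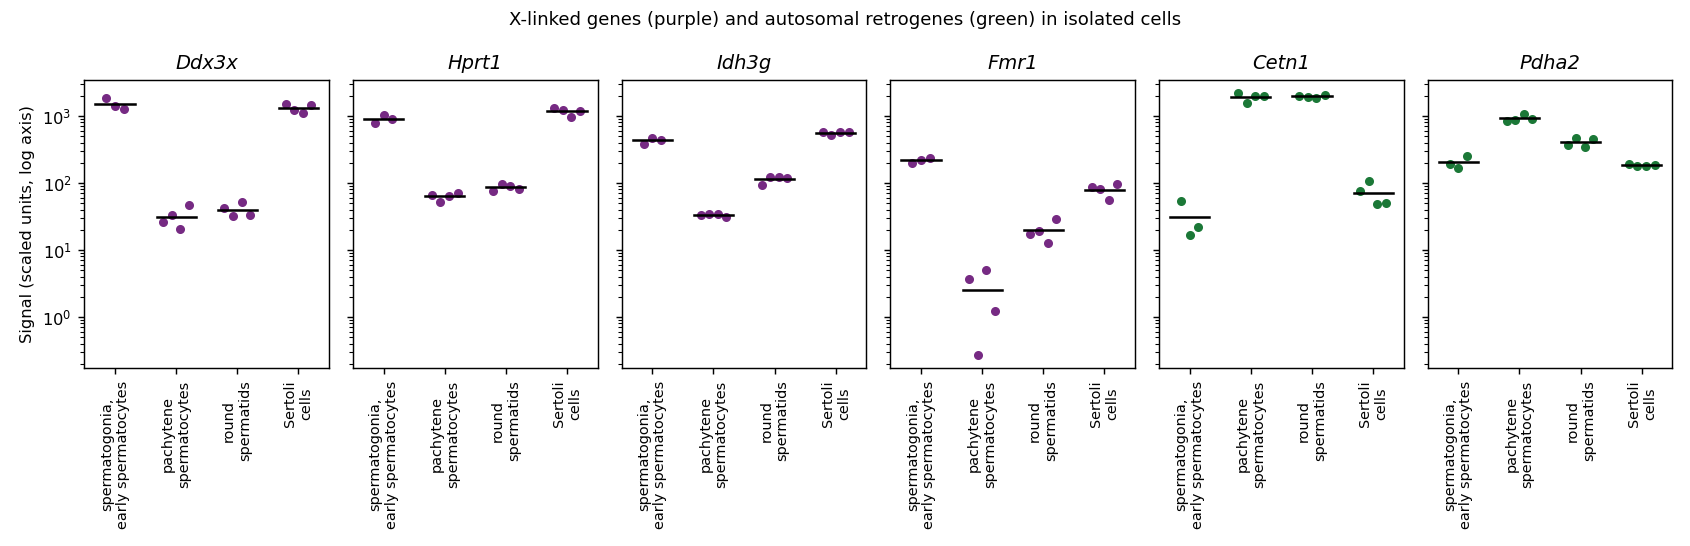
Array signal (log axis) of X-linked housekeeping genes and autosomal retrogenes in the isolated cell groups, with 1 point per sample and a bar at each mean. Ddx3x is at 1506 in spermatogonia plus early spermatocytes and 31.3 in pachytene spermatocytes, where Cetn1 is at 1947.

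Of the germ cell lists, pachytene genes were higher in 7 of 8 cases (median 1.92, adjusted p = 0.00181, 0.0327 with an estimated correlation), with Ccna1 60.7-fold, the acrosin gene Acr 36.0-fold and the lactate dehydrogenase gene Ldhc 5.13-fold higher. Acrosome genes were higher in 10 of 11 (median 3.22, adjusted p = 6.48e-05, 0.061 with an estimated correlation), with Adam2 36.4-fold and Zpbp 26.7-fold, and elongating spermatid genes in 15 of 15 (median 5.58, adjusted p = 1.29e-07, 0.155 with an estimated correlation). In the G2 and M phase list, 6 of 20 were higher (median 0.49, adjusted p = 0.0162, 0.321 with an estimated correlation), among them Aurka (8.87-fold) and Aurkc (6.33-fold), and its adjusted p was 0.0872 with quantile normalization, in a range of 0.00761 to 0.0872. DNA replication genes were lower in 10 of 17 and higher in 1, Rfc4 (median -1.16, adjusted p = 0.0204, 0.198 with an estimated correlation), with the helicase gene Mcm2 falling from 280 ± 11.1 to 5.00 ± 0.860 (-4.82). Spermatogonia genes were lower in 8 of 10 (median -2.12, adjusted p = 0.00652, 0.061 with an estimated correlation), with Sohlh1 at -3.23 and Dmrt1 at -2.68. In the meiotic recombination list, Mlh3 (3.68-fold) and the cohesin gene Stag3 (2.91-fold) were higher and the synaptonemal gene Sycp1 (-1.12) lower of 7 (adjusted p = 0.144).

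Somatic lists were mostly lower in pachytene spermatocytes. Leydig genes were lower in 10 of 11 cases (median -3.52, adjusted p = 1.83e-04, 0.061 with an estimated correlation), with Hsd3b1 falling from 2758 ± 832 to 39.2 (-6.19), and macrophage and blood genes in 9 of 9 (median -3.96, adjusted p = 2.90e-04, 0.0327 with an estimated correlation), with Hbb, for haemoglobin, falling from 1189 ± 398 to 8.69 (-6.38). Immediate early and heat shock genes were lower in 14 of 14 (median -5.18, adjusted p = 5.36e-07, 0.0782 with an estimated correlation), with Fosb falling from 1852 ± 277 to 22.3 (-6.09). Sertoli cell genes were lower in 11 of 14 (median -2.12, adjusted p = 7.82e-04, 0.0703 with an estimated correlation), such as Kitlg (-4.45), for the Kit ligand. Proteases and inhibitors were lower in 13 of 15 (median -3.00, adjusted p = 6.23e-05, 0.0327 with an estimated correlation), such as Timp1 (-5.78). Junction genes were lower in 8 of 13 (median -2.10, adjusted p = 0.0163, 0.061 with an estimated correlation), and Nectin3 was 5.32-fold higher. Myoid genes were lower in 3 of 7 (adjusted p = 0.146), Myl9 (-4.82), Myh11 (-1.59) and Acta2, which lost its call without replicate 2 of spermatogonia plus early spermatocytes (adjusted p = 0.0656, the highest over the alternatives, where the lowest was 3.07e-05). Endothelial genes were lower in 2 of 6 (adjusted p = 0.55), Eng and Esam, and the adjusted p of Esam was between 0.00545 and 0.172 over the alternatives. Retinoid genes were lower in 7 of 14 (adjusted p = 0.114), among them the retinoic acid hydroxylase gene Cyp26b1 (-4.60), and the synthesis gene Aldh1a2 was 9.49-fold higher. Of 10 cholesterol synthesis genes, Fdft1 (3.92-fold) and Mvd (5.09-fold) were higher, and Cyp51 (-2.45), Dhcr7 (-2.12) and Lss lower (adjusted p = 0.981). For Mlh3, Myh11 and Nectin3, 1 other probe set each was not called. Counts adjusted over the list alone were the same for every list.

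Round spermatids were compared with pachytene spermatocytes to find the changes across the meiotic divisions. Acrosome, flagellum and X-linked lists were higher in round spermatids at the preset correlation between genes, but none of the 3 passed with an estimated one. Single genes of recombination, such as Spo11, and of the piRNA pathway, which guards the germ line against transposons, such as Tdrd1, were lower, although the lists that hold them did not pass. Beside these values, the 3' to 5' ratio of GAPDH was higher in round spermatids (2.13) than in pachytene spermatocytes (1.22). For actin, the ratio was 1.90 ± 0.0962 in round spermatids and 2.23 ± 0.231 in pachytene spermatocytes.

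Of 20253 probe sets, 1802 were higher and 2660 lower in round spermatids. Tmem131l rose from 10.4 ± 3.03 to 436 ± 30.9 (28.9-fold, adjusted p = 8.63e-13), 1700122O11Rikl 24.0-fold, Tmem89 from 31.8 ± 20.4 to 740 ± 81.9 (22.1-fold), Cnih2 20.5-fold, the cytokine gene Mif from 13.5 ± 4.88 to 353 ± 16.5 (19.7-fold) and the cytokine gene Il11 from 6.17 to 202 ± 28.3 (18.3-fold). Fbxo9, for a ubiquitin ligase subunit, went from 319 ± 38.6 to 6.92 (-4.89, adjusted p = 3.26e-11), B3galnt1 from 733 to 34.4 (-4.27), Mlh3 from 158 ± 28.2 to 3.64 (-4.21), Phf2 from 1032 ± 42.4 to 60.9 ± 4.03 (-3.98) and the ribosomal protein gene Rpl19 from 1162 to 75.8 (-3.93), and Hace1 changed by -4.11. Samples of the 2 groups did not overlap for any of these genes.

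In the elongating spermatid list, 11 of 15 genes were higher in round spermatids and none lower (median 1.76, camera adjusted p = 2.45e-04, 0.573 with an estimated correlation), with the flagellar genes Tsks 6.61-fold and Akap4 6.17-fold higher. The acrosome list had 5 of 11 higher (median 0.54, adjusted p = 0.0169, 0.573 with an estimated correlation), with Spam1 at 1771 ± 85.0 (7.83-fold), Spaca3 at 1693 ± 6.13 (7.75-fold) and Acrv1 at 1545 ± 42.1 (7.45-fold). With quantile normalization the acrosome list's adjusted p was 0.085, in a range of 0.01 to 0.085. The X-linked list had 7 of 18 higher and none lower (median 0.48, adjusted p = 0.00108, 0.12 with an estimated correlation), with Idh3g rising from 33.4 ± 1.52 to 115 ± 13.6 (3.09-fold) and Usp9x 3.03-fold, while Ddx3x and Hprt1 were not called. In the Tsks, Akap4, Spam1, Spaca3, Acrv1, Idh3g and Usp9x values, all round spermatid samples lay above all pachytene samples.

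The other lists did not pass in this comparison. The meiotic recombination list had 4 of 7 lower and 1, Smc1b, higher (median -1.22, adjusted p = 0.158), with the recombination endonuclease gene Spo11 at -2.86 and the synaptonemal gene Sycp2 at -1.60. The pachytene list had 3 of 8 lower and 2 higher (adjusted p = 0.353). The lower ones were the piRNA genes Tdrd1, from 2267 to 274 (-3.02), and Piwil2 (-2.71), and the regulator gene Mybl1 (-2.71), and the higher ones Acr (4.08-fold) and Ccna1. The G2 and M phase list had 6 of 20 lower (adjusted p = 0.296), such as Cdc20 (-2.64), with Ccnb1 3.00-fold higher. Retrogenes were lower in 2 of 3 (adjusted p = 0.158), Cstf2t (-2.65) and Pdha2 (-1.15). The cholesterol synthesis list had 3 higher and 2 lower of 10 (adjusted p = 0.553), with Cyp51 6.97-fold and Sqle 3.15-fold higher, and its median (-0.02) and mean (0.22) differed in sign. DNA replication genes were 1 higher and 2 lower of 17 (adjusted p = 0.986), with a median of 0.06 and a mean of -0.09.

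Few genes of the somatic lists differed between round spermatids and pachytene spermatocytes. No gene was called by limma among 14 Sertoli cell genes (adjusted p = 0.553), 11 Leydig genes (adjusted p = 0.986, with a median of -0.12 and a mean of -0.05, where camera's direction was up) and 9 macrophage and blood genes (adjusted p = 0.605), and 6, 1 and 0 of them had an unadjusted p under 0.05. Of the other lists, Ret was higher of 10 spermatogonia genes (adjusted p = 0.224), Myh11 of 7 myoid genes (adjusted p = 0.423), Rdh10 of 14 retinoid genes (5.15-fold, adjusted p = 0.549) and Eng of 6 endothelial genes (adjusted p = 0.842), where none passed adjusted over the list alone. Ctnnb1 was lower of 13 junction genes (adjusted p = 0.398), Timp2 higher and Serpina5 lower of 15 proteases and inhibitors (adjusted p = 0.498), and Nr4a1 higher and Jun lower of 14 immediate early genes (adjusted p = 0.224). Of these, Ctnnb1 (-1.01), Jun (-1.15) and Sycp1 (-1.22) were less than 2-fold lower with quantile normalization, at -0.75, -0.94 and -0.96. Ctnnb1, Jun and Serpina5 were also less than 2-fold lower without single samples, for example at -0.95 and -0.99 without round spermatid replicate 3 and at -0.75 without replicate 4. The adjusted p of Eng was between 0.00326 and 0.149 over the alternatives. The other counts adjusted over the list alone were the same. At least 1 other probe set was not called for each of Mlh3, Ccna1, Cdc20, Ccnb1, Rdh10, Timp2, Usp9x and Jun.

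Probe sets enriched in 1 isolated cell group were followed through the stages to place each cell type's transcripts in the cycle. Nearly all transcripts enriched in pachytene spermatocytes and round spermatids were stage-regulated, the former with peaks at IX-XI to XIII-XIV and the latter with most at IV-V to IX-XI. Transcripts enriched in Sertoli cells were stage-regulated more often than other transcripts, and those enriched in spermatogonia plus early spermatocytes less often. The latter preparation came from younger rats and also had macrophage, Leydig and immediate early lists at medians of 3.47, 3.21 and 4.27 above tubules, so that its class is not one of germ cell transcripts alone. The Sertoli class is likewise not one of Sertoli cell transcripts alone, since Leydig and immediate early lists were 3.12 and 3.77 above tubules in that preparation, and myoid and endothelial lists were 2.93 and 2.64 above the mean of all samples. Later spermatids were not isolated, so that the round spermatid class may hold transcripts that later spermatids have as well. As the cell types along a tubule change with stage, a transcript of 1 cell type can vary through the mix of cells alone. The shares therefore do not show regulation within a cell. Fisher's exact test took probe sets as independent, although several can share a gene or a cell type. Of 6794 stage-regulated probe sets tested in both fits, 649 (9.55%) were enriched in 1 cell group.

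Of 405 probe sets enriched in round spermatids and tested in tubules, 371 were stage-regulated (91.6%, against 34.9% of the other probe sets, Fisher's exact test, odds ratio 20.4, adjusted p = 8.17e-124), with 117 peaks at stage VI, 64 at IV-V, 56 at IX-XI, 54 at VIIc.d and 45 at VIIa.b. The lowest stage was XIII-XIV for 122 of them. Tmem89, Il11 (141 ± 25.7 at VIIa.b, 6.75-fold) and Mtnap1 (1068 ± 102 at VIIa.b against 20.2, 42.7-fold) had the largest margins over the other cells. Of 49 probe sets enriched in pachytene spermatocytes, 47 were stage-regulated (95.9%, against 36.0%, odds ratio 41.8, adjusted p = 9.75e-19), with 26 peaks at XII, 12 at IX-XI and 9 at XIII-XIV, and 28 were lowest at IV-V. Phf2, Prok2 (214 ± 48.3 at XII, 6.85-fold) and Traf2 (336 ± 65.4 at XIII-XIV, 17.1-fold) stood first among them. Of 333 Sertoli-enriched probe sets, 209 were stage-regulated (62.8%, against 35.6%, odds ratio 3.04, adjusted p = 6.41e-23), with 37 peaks at VIIa.b and 33 at VIII, and VIIa.b was also the lowest stage for 29 of them, more than any other stage. Prnd, Ptgds (460 ± 46.4 at VIIc.d, 7.06-fold) and Cst9l (1427 ± 159 at VI, 4.85-fold) had the largest margins.

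Of 142 probe sets enriched in spermatogonia plus early spermatocytes, 22 were stage-regulated (15.5%, against 36.3%, odds ratio 0.322, adjusted p = 5.68e-08), and without a filter on low values the shares were 9.43% and 25.1%. Among these were Vit, for an extracellular matrix protein (669 ± 21.7 in spermatogonia plus early spermatocytes, 2.44-fold between stages), the chemokine gene Ccl4 (481 ± 43.6, 3.06-fold) and the non-coding RNA gene Meg3 (731 ± 295, 2.14-fold), which came to under 2-fold without replicate 5 of stages XIII-XIV (log2 0.94). The class as a whole held 288 probe sets, against 473, 51 and 408 for Sertoli cells, pachytene spermatocytes and round spermatids, and 175, 147 or 164 without replicate 1, 2 or 3 of its own 3 samples. The peaks of the stage-regulated members were distributed differently from those of other stage-regulated probe sets for the Sertoli, pachytene and round spermatid classes (permutation test, adjusted p = 1.33e-05 each, from the smallest p that permutations can give), but not detectably for spermatogonia plus early spermatocytes (adjusted p = 0.481).

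**Figure D4:**
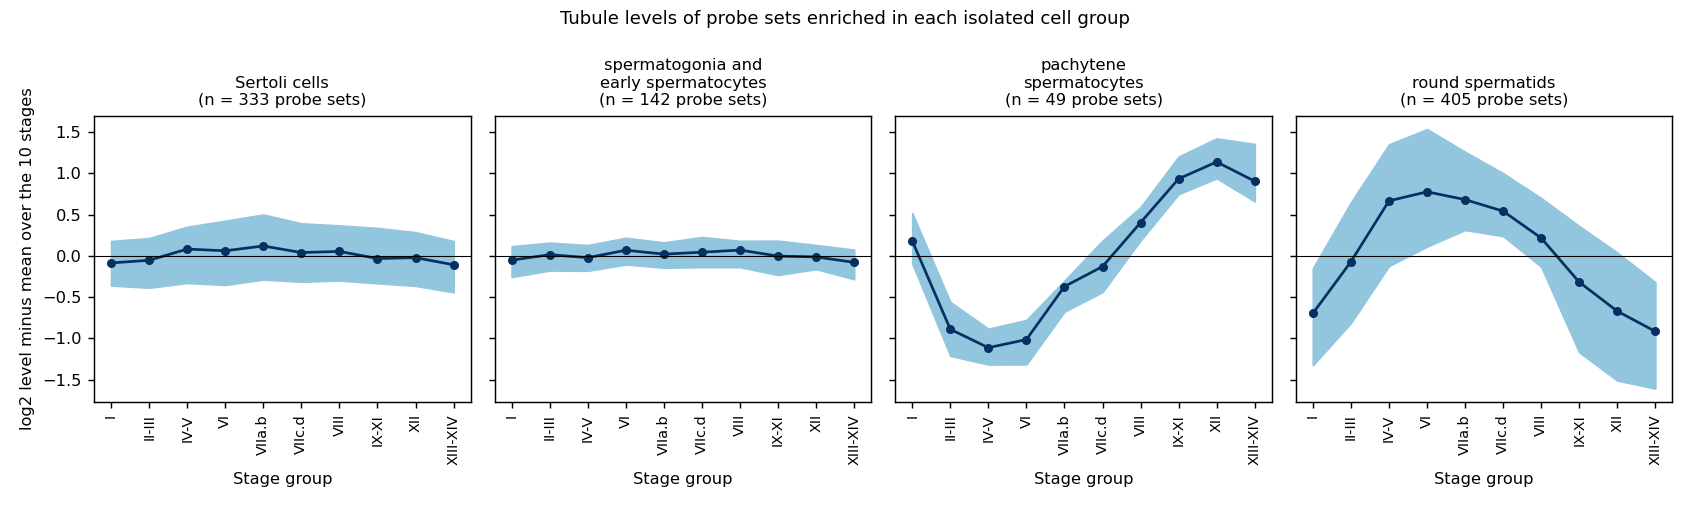
Log2 level minus the mean over the 10 stages (y axis) against stage group, as the median (line) and the interquartile range (band) of the probe sets enriched in each isolated cell group and tested in tubules, 1 panel per cell group. The pachytene line runs from -1.11 at IV-V to 1.14 at XII, and the round spermatid line from -0.92 at XIII-XIV to 0.78 at VI.

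Whole testis was compared with the mean of the stages to look for transcripts of cells outside the dissected tubules. The labels give no age for these rats and only the tubules were dissected, so that the comparison is not one of location alone. Whole testis had higher levels of the genes of Leydig cells, which make androgens between the tubules, and of macrophages and blood. Immediate early genes such as Fos and Egr1 were lower in whole testis than in dissected tubules. Among the germ cell lists, the G2 and M phase list alone passed its test, with a small change against a mean of log2 levels, which lies below the mean signal where levels vary by stage.

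Of 22504 probe sets, 520 were higher and 269 lower in whole testis, and 71 and 7 at 4-fold. With a pseudocount of 1, 674 were higher and 575 lower, so that the excess of higher ones depended on this choice. The steroid enzyme genes Cyp17a1 (588 ± 74.7 against 9.14 in tubules, 46.0-fold, adjusted p = 8.78e-22) and Hsd3b1 (294 ± 42.8 against 11.2, 22.6-fold) were higher, as were the esterase gene Ces1d (601 ± 155, 23.1-fold), the Leydig peptide gene Insl3 (896 ± 241 against 52.4, 16.2-fold) and the selenium transport gene Selenop (4739 ± 1075 against 339, 14.5-fold). The chemokine gene Cxcl1 was lower, at 4.75 ± 4.87 against 105 (-3.45, adjusted p = 1.1e-19), followed by Fos (5.43 ± 5.66 against 81.1, -3.11), Lgals2 (-1.97), Nfkbiz (-1.93) and Epha3 (-1.90). Whole testis samples did not overlap tubule samples for these genes, except for Nfkbiz and Epha3.

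The Leydig list had 8 of 11 genes higher and none lower (median 1.61, camera adjusted p = 1.76e-13, 2.33e-07 with an estimated correlation), and the macrophage and blood list 5 of 6 higher (median 2.22, adjusted p = 4.96e-06, 9.42e-05 with an estimated correlation), with Hbb at 330 ± 143 (12.8-fold) and the complement gene C1qa 5.89-fold. The immediate early and heat shock list had 6 of 11 lower and none higher (median -1.10, adjusted p = 3.93e-09, 5.93e-04 with an estimated correlation), with Egr1 at 46.7 ± 19.5 against 144 (-1.56) and Jun at -1.26. Proteases and inhibitors had 4 of 15 higher (median 0.68, adjusted p = 7.54e-08, 9.92e-05 with an estimated correlation), Ctsb (2.56-fold), Timp1 (3.86-fold), Timp2 (2.24-fold) and Ctsl. The junction list had 2 of 13 higher (median 0.47, adjusted p = 2.49e-04, 0.00395 with an estimated correlation), Espn (527 ± 226, 6.23-fold) and Cldn5, an endothelial and Sertoli cell gene. Samples of Hbb, C1qa, Egr1, Jun, Ctsb and Espn did not overlap between whole testis and tubules.

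Smaller shifts of whole lists were found with 1 or 2 called members. The myoid list had Cnn1 of 6 genes higher (median 0.44, adjusted p = 0.00478, 0.0366 with an estimated correlation), and Cnn1 came to less than 2-fold when single samples were left out, at least 0.94. The G2 and M phase list had Aurka of 20 (median 0.28, adjusted p = 0.00543, 0.0126 with an estimated correlation), the Sertoli cell list Ctsl and Inhbb of 14 (median 0.28, adjusted p = 0.00641, 0.0224 with an estimated correlation) and the X-linked list Smc1a of 18 (median 0.22, adjusted p = 0.00744, 0.00924 with an estimated correlation). The acrosome list did not pass (Spam1 of 11 higher, adjusted p = 0.0736), but passed with quantile normalization (adjusted p = 0.0111) and without whole testis replicate 2 (adjusted p = 0.0471), in a range of 0.0111 to 0.131. Because of this mean of log2 levels, small rises of lists with many stage-regulated genes, such as the G2 and M phase list (17 of 20), need not be rises in mean signal. Ctsl and Spam1 were 2.18-fold and 2.79-fold higher although their mean signals were close, at 801 against 711 and 920 against 901.

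No gene was called by limma in whole testis among 7 spermatogonia genes (adjusted p = 0.948, with a median of -0.00 and a mean of 0.04), 8 meiotic recombination genes (adjusted p = 0.691), 14 DNA replication genes (adjusted p = 0.948, with a median of -0.01 and a mean of 0.08), 10 cholesterol synthesis genes (adjusted p = 0.453) and 3 retrogenes (adjusted p = 0.734). In this order, 2, 3, 7, 6 and 3 of them had an unadjusted p under 0.05. Of the remaining lists, Acr was lower of 8 pachytene genes (adjusted p = 0.131), Tnp2 higher of 15 elongating spermatid genes (adjusted p = 0.453), Eng of 4 endothelial genes (adjusted p = 0.378) and Aldh1a1 of 16 retinoid genes (adjusted p = 0.478, with a median of -0.04 and a mean of 0.04). Without single whole testis samples, Acr (-1.21), Tnp2 (1.03) and Aldh1a1 (1.04) came to -0.87, 0.89 and 0.96 and were not called. The mean signals of Tnp2 were 8542 and 5971. None of the other probe sets of Fos, Nfkbiz, Epha3, Ctsl, Timp2 and Jun was called. Counts adjusted over the list alone were the same for every list.

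**Figure D5:**
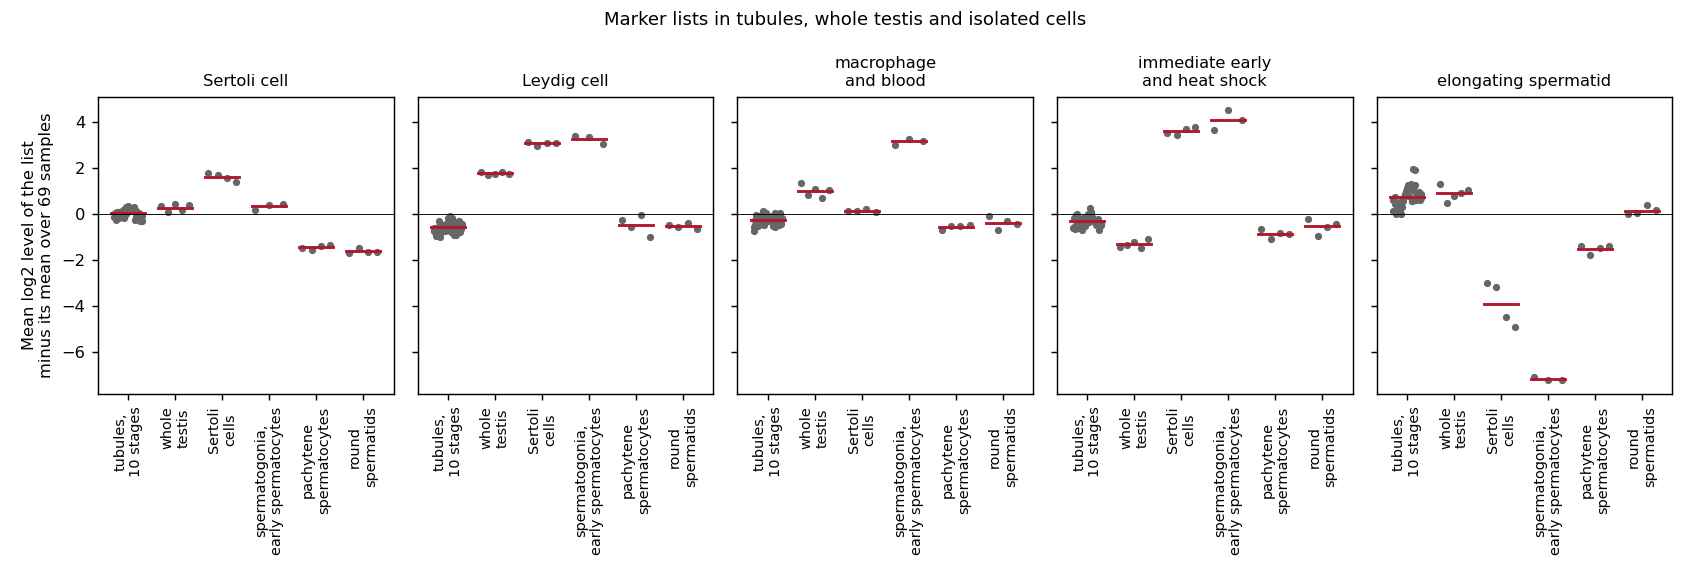
Mean log2 level of the genes of 5 lists minus its mean over the 69 samples (y axis) in tubules, whole testis and isolated cells, with 1 point per sample and a bar at each group's mean. Relative to tubules, the Leydig list is higher by a median of 3.12 in Sertoli cells, 3.21 in spermatogonia plus early spermatocytes and 1.61 in whole testis, and the immediate early list by 3.77 and 4.27, but not in whole testis (-0.72).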

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

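All tests in this part were chosen only after the results were seen, except the comparison of the immediate early list with random lists, which tests handling of the dissected tubules.

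Leydig cell genes stood far above their tubule level in isolated Sertoli cells, with Insl3 at 1793 ± 258 against 52.4, Cyp17a1 at 1324 ± 208 against 9.14 and Hsd3b1 at 1220 against 11.2. Whole testis, which holds Leydig cells, had lower signals of Insl3 (896), Cyp17a1 (588) and Hsd3b1 (294) than isolated Sertoli cells. The macrophage and blood list of isolated Sertoli cells was only 0.21 above tubules. Of the Leydig list's 11 genes, 7 passed the filter in tubules and none is on another list. The labels give about 85% purity for Sertoli cells and name no step that removes interstitial cells. RNA from Leydig cells in the preparation would make the Leydig list fall more than the Sertoli list from isolated Sertoli cells to tubules. For the 3 genes above, though, it would have to exceed its level in whole testis, without a like rise of the macrophage list. The Leydig list changed by a median of -3.12 (n = 11) and the Sertoli list by -1.59 (n = 14), a difference of -1.53 (permutation test, p = 0.0413). The permutation took genes as independent, and its p-value may be too small. Over the isolated cells, the Leydig genes had an estimated correlation of 0.168. The difference also rests on the same levels that set the pattern. It thus does not decide on expression of the list as a whole by Sertoli cells at the level they have in tubules. Only 4 of 11 Leydig genes fell by more than the Sertoli list gene that changed most (-3.45), against 9 of 11 for the median one. At most for these 4, the values argue against such expression. Expression that rose during isolation was not tested. In spermatogonia plus early spermatocytes the list was 3.21 above tubules, with Cyp17a1 at 2970 ± 698, and there RNA from Leydig cells and a difference of the younger testis cannot be told apart, because age goes with the group, while elutriation gave 85% to 95% purity.

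Immediate early genes were lower in whole testis than in tubules. Dilution by interstitial RNA in whole testis is argued against, since the list changed by a median of -0.72 (n = 14) and the Sertoli and germ cell lists by 0.09 (n = 66), a difference of -0.81 (permutation test, p = 1e-04, the smallest permutations can give). The permutation took genes as independent, so that its p-value may be too small and does not measure the spread over samples. The 11 genes of the list tested in the contrast had a median of -1.10. Within stages, 11 of these genes varied together over the tubule samples (mean pairwise correlation 0.153, against an upper percentile of 0.0745 for random lists), but so did the elongating spermatid (0.588), acrosome (0.149) and recombination (0.116) lists, so that handling of the tubules during dissection cannot be told apart from genes that are expressed together. Isolated Sertoli cells and spermatogonia plus early spermatocytes were higher than tubules by 3.77 and 4.27, but pachytene spermatocytes (-0.61) and round spermatids (-0.20) were not. A biological difference between tubules and whole testis remained untested. For the comparison on dilution, the mean of log2 levels in tubules raises the change of stage-regulated genes, which the Sertoli and germ cell lists hold. The Sertoli cell list, with 4 of 14 such genes, had a median change of 0.28.

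Transcripts of spermatids were found in the other cell preparations, with Prm1 at 5389 in round spermatids, 4027 in pachytene spermatocytes and 1418 ± 839 in Sertoli cells, and Tnp1 at 4255, 2283 and 787. Round spermatids like those isolated would bring all their abundant transcripts to a preparation. For this, the 10 lowest of 1922 other genes with a signal of at least 400 in round spermatids were used. They allow a share of at most 11.7% in pachytene spermatocytes and 2.43% in Sertoli cells. In pachytene spermatocytes the elongating spermatid list had a median of 21.5% to 34.6% of the round spermatid level. This was above the allowed share by 1.99-fold or more in 4 of 4 samples. It argues against round spermatids with the transcripts of those isolated as the source of the list's level. Genes behind the allowed share can vary with stage, such as Tmem89 (81.2-fold, highest at VI) and Itih3 (69.1-fold, highest at IV-V). Round spermatids of other stages could lack such transcripts, so that the test does not cover them. In Sertoli cells the list's median was above the allowed share in 3 of 4 samples and below it (0.762-fold) in replicate 4, so that round spermatids and another source cannot be told apart for the list, because the samples differ, although 6 of its 15 genes, Prm1 (26.3%) and Tnp1 (18.5%) among them, and the acrosome list's median (up to 7.56%) were above the allowed share in every sample. The elongating spermatid and acrosome lists, which round spermatids in a preparation would bring alike, differed from round spermatids by medians of -4.46 and -4.00 in Sertoli cells (permutation test between the lists, p = 0.627) and of -1.76 and -1.05 in pachytene spermatocytes (p = 0.28), and no difference between them was detected, while RNA of later spermatids and transcription before the meiotic divisions were not tested.

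Other splits of the samples into groups of the same sizes tested whether chance can account for the counts. Each comparison had 100 splits, the real one included, and the 2 contrasts between germ cell groups had 35. The real split gave the most calls for the stage-regulated probe sets (7240, highest other split 289) and list members (99, other 8). It also did for Sertoli cells against germ cells (10900, other 8602), round spermatids against pachytene spermatocytes (4462, other 2) and whole testis (789, other 634). For pachytene spermatocytes against spermatogonia plus early spermatocytes it gave 9541 (other 7378, where pachytene replicate 2 was grouped with spermatogonia plus early spermatocytes). In each of these, 1 split, the real one, gave as many. Other splits still mix real differences, samples were taken as independent, and no correction over the comparisons was made. Chance is thus made unlikely but not excluded. For the Sertoli (473), spermatogonia plus early spermatocyte (288), pachytene (51) and round spermatid (408) classes, the highest other split gave 0. A group of mixed cell types can hardly be 4-fold above each other group, so that these splits say little about chance. Among adjacent stages, with the same limits, 1 of 100 splits, the real one, gave as many for I to II-III (810, other 319), II-III to IV-V (472, other 174), VI to VIIa.b (482, other 159), VIIa.b to VIIc.d (249, other 58), VIIc.d to VIII (118, other 54), VIII to IX-XI (758, other 311), IX-XI to XII (297, other 146), XII to XIII-XIV (208, other 55) and XIII-XIV to I (311, other 133). From IV-V to VI, 2 of 100 splits gave as many (104, other 107), and the other was the real split with stage VI replicate 1 moved to stage IV-V. Without stage VI replicate 1 the count was 141, and with replicate number as a block 114.

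Single samples lay far from the rest of their group in 3 of 70 groups of array measures and 15 of 116 groups of signals of named genes, where chance gives about 1 in 20. The measure is the gap of the extreme sample to the next, divided by the group's range. Stages IX-XI replicate 5 had 52.6% of probe sets above 43.7, against 51.7% to 51.9% in the others (0.741). Stage VIII replicate 1 had a mean correlation with its group of 0.920, against 0.932 to 0.935 (0.792). Stage II-III replicate 1 had a GAPDH 3' to 5' ratio of 0.959, against 1.18 to 1.25 (0.762). Most of the tubule samples set apart for genes were numbered 1. At stage VIIa.b, replicate 1 was high for Prnd (2088 against 1804 to 1857, 0.812) and Fam209 (3398 against 2890 to 3031, 0.723). Replicate 1 was low for Vit at stage VI (103 against 160 to 175, 0.788) and high for Smco4 at IX-XI (18.6 against 5.45 to 7.77, 0.824), Numbl at XII (24.1 against 5.61 to 7.96, 0.873) and Gstp1 at VIIc.d (26.5 against 11.9 to 15.2, 0.773). Zbtb5 was high in replicate 3 of XIII-XIV (380 against 317 to 334, 0.724), Prss37 low in replicate 3 of IV-V (12.2 against 49.1 to 50.9, 0.954) and Il11 high in replicate 4 of XII (44.7 against 8.20 to 14.2, 0.836).

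In isolated cells, Serpina5 was high in Sertoli replicate 2 (3536 against 2281 to 2483, 0.839), Phf2 low in round spermatid replicate 1 (54.9 against 62.3 to 63.6, 0.853), Tmem89 high in pachytene replicate 1 (62.1 against 18.8 to 25.5, 0.844) and Mif high in pachytene replicate 4 (20.8 against 10.6 to 11.7, 0.889). In whole testis, Cxcl1 was high in replicate 1 (13.3 against 1.97 to 4.21, 0.802) and Epha3 low in replicate 4 (6.33 against 8.48 to 9.31, 0.721).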

How the results depend on the processing

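Leaving out the tubule samples numbered 1 was an alternative chosen only after the data were seen.

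Stage-regulated probe sets numbered 7568 with a pseudocount of 1, 7736 without a filter, 7191 with quantile normalization, 7381 with replicate number as a block and 7392 without the tubule samples numbered 1, against 7240. These settings kept 99.1%, 98.1%, 95.4%, 99.1% and 93.0% of the 7240 probe sets, and of those kept, 99.7%, 100%, 92.1%, 98.3% and 87.3% had the same peak stage. Without single samples the count was 7170 to 7330, at least 97.1% of calls were kept, and at least 96.2% of these had the same peak.

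Between whole testis and tubules, a pseudocount of 1 gave 1249 probe sets, 674 higher and 575 lower, against 789. The cause was not tested. The count was 798 with the block, 782 without the tubule samples numbered 1 and 767 to 994 without single samples.

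Probe sets enriched in spermatogonia plus early spermatocytes numbered 147 to 310 without single samples, against 288, and were 175, 147 and 164 without replicate 1, 2 or 3 of that group, which leaves it with 2 samples. The other classes held 441 to 492 (Sertoli cells), 46 to 55 (pachytene spermatocytes) and 380 to 414 (round spermatids) without single samples.

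In the 3 cell contrasts, in the order Sertoli, pachytene, round spermatid, there were 10906, 9582 and 4461 probe sets with the block, 14295, 10750 and 4929 without a filter, 9871, 9732 and 4365 with quantile normalization, 11438, 9904 and 4891 with a pseudocount of 1, and 10431 to 10892, 9049 to 9599 and 4391 to 4551 without single samples, against 10900, 9541 and 4462. The step from IV-V to VI had 83 to 141 probe sets without single samples, 114 with the block and 156 without the tubule samples numbered 1, and the step from IX-XI to XII had 404 without the latter, against 297. Without a filter, the median log2 change of all probe sets between Sertoli and germ cells was -0.33 in place of -0.15, over more probe sets with low signal. With quantile normalization, the median of all probe sets between pachytene spermatocytes and spermatogonia plus early spermatocytes changed its sign, from -0.15 to 0.13. From IX-XI to XII, 143 probe sets rose and 154 fell, but 160 rose and 133 fell with quantile normalization, and 220 and 184 without the tubule samples numbered 1. From VIIa.b to VIIc.d, 137 rose and 112 fell, but 153 and 160 without the latter.

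Of 326 genes and contrasts named, all kept their direction and call with the block, without a filter and with a pseudocount of 1. With quantile normalization 6 of 325 lost the call, without single samples 18 of 326 lost it for at least 1 sample, and without the tubule samples numbered 1 it was lost by 4 of 119, Ret, Star, Eng and Jam3. Of 76 list tests, 3 lost significance with quantile normalization, the G2 and M phase and retrogene lists in pachytene spermatocytes (adjusted p = 0.0872 each, from 0.00761 and from 0.0185 over the alternatives, with medians of 0.42 to 0.59 and 2.02 to 2.31) and the acrosome list in round spermatids (adjusted p = 0.085, from 0.01, with medians of 0.33 to 0.58). The acrosome list in whole testis gained it with quantile normalization (adjusted p = 0.0111) and without whole testis replicate 2 (adjusted p = 0.0471), in a range of 0.0111 to 0.131 with medians of 0.13 to 0.20. The elongating spermatid list in Sertoli cells gained it without Sertoli replicate 1 (adjusted p = 0.0274) or 2 (adjusted p = 0.0167), in a range of 0.0167 to 0.195 with medians of -1.77 to -1.16. None of the 326 genes changed direction under these alternatives. Among lists that did not pass, medians near 0 changed sign in some, and that of the macrophage and blood list in Sertoli cells (-0.74) was 0.03 to 0.14 without single samples of spermatogonia plus early spermatocytes.

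The labels do not say whether tubule samples with the same number came from the same rats. Their deviations from stage means gave a hint: 37 of 49 tubule samples correlated best with samples of their own number, 39 of 216 pairs with the same number had a correlation above 0.1, and those numbered 1 had a mean correlation of 0.139. The arrays' signal limits all calls on weak genes, since no detection calls were given and 41.7% to 59.5% of probe sets lay above 43.7 per array.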

Other observations

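The choice of transcripts in this part was made only after the data were seen, and no explanation was tested.

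Some transcripts were far higher in tubules of stages VIIa.b to IX-XI than in any of the isolated cells. Of 7240 stage-regulated probe sets, 33 had a level at their peak stage at least 4-fold above each of the 4 isolated cell groups, and they represented 23 genes. Their peaks lay at stage VIII (18), IX-XI (8), VIIc.d (6) and VIIa.b (1), and none lay at the other 6 stage groups, although these held many stage-regulated probe sets, such as 904 at XIII-XIV and 797 at VI. Round spermatids had the highest level among the isolated cells for all of the genes given here. Their GAPDH 3' to 5' ratio was 2.13, against 1.54, 1.34 and 1.21 at stages VIIc.d, VIII and IX-XI. For actin, the ratio was 1.90 in round spermatids, against 2.21, 1.94 and 2.08. The part of RNA quality in these differences was not tested.

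Fbxo2, for a glycoprotein-binding ubiquitin ligase subunit, was 143 ± 19.7 at stage VIII and 5.49 in round spermatids, and the receptor gene Ephb3 was 154 ± 28.0 and 11.5. Syne3, for a protein of the nuclear envelope, was 262 ± 29.0 at stage VIII and 45.1 in round spermatids, Leng1 351 ± 46.2 and 53.6, and Garin4 1496 and 314. The phospholipid enzyme gene Pcyt1a was 688 ± 120 at stage VIII against 167. Gfra1, for a receptor of stem spermatogonia, was also among them, at 628 against 158, while another probe set of Gfra1 was not stage-regulated. At stage VIIc.d, Abhd2, for a sperm lipid hydrolase, was 2452 ± 132 against 601 in round spermatids, and the mitochondrial topoisomerase gene Top1mt 679 ± 74.3 against 128. At IX-XI, the kinesin light chain gene Klc3 was 1220 ± 324 against 242, the protamine gene Prm2 8135 against 1753 and Prss37 4465 against 1097.

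The macrophage and blood list had its highest median in spermatogonia plus early spermatocytes, at 3.47 above tubules, where Hbb reached 1189 ± 398. In Sertoli cells, by contrast, the macrophage and blood list was close to tubules (0.21).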
